A study of Mus musculus with 6 samples.

How the data were processed

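RNA was measured in whole mouse retina of 2 genotypes, with 3 libraries from wild-type retinas (Unc119+/+) and 3 from retinas lacking a functional Unc119 gene (Unc119−/−, called knockout here). Per the labels, total RNA was extracted with TRIzol and libraries were made with a stranded mRNA kit. The labels number the libraries 1 to 3 within each genotype and do not say that each came from a separate animal. The p-values therefore measure the spread between these libraries, part of which may be technical. Age, sex and batch are not given in the sources used here.

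Per the submitters' processing notes, the reads were handled with TopHat2 2.1.1 and Cuffdiff 2.2.1 on the mm10 mouse genome. Neither the gene annotation nor the strand setting of the counting is given in the sources used here. The authors deposited 1 table per library with an FPKM value (fragments normalised to transcript length and to the number of mapped fragments) for each gene symbol, as the file headers name the unit. FPKM divides by transcript length and by library size, so the values are not counts, the number of fragments behind each value is unknown, and a gene that takes a larger share of a library can lower the values of the others. How the values were scaled between libraries is not given in the sources used here. Median-of-ratios factors ran only from 0.998 in knockout replicate 3 to 1.002 in wild-type replicate 2. The values were thus already level by that measure, and rescaling by it could change little.

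Each table listed the same 24346 gene symbols, and no pair of libraries held identical values. Between libraries the correlation of log2(FPKM + 1) across genes ran from 0.983 to 0.993. The absolute depth is unknown. Relative depth was read from the commonest ratio between libraries of genes with an FPKM of at most 0.3, counting ratios within 0.015 log2 units of it. Set against wild-type replicate 2 as 1, it was 0.763 and 0.805 in wild-type replicates 1 and 3, and 0.935, 0.931 and 0.964 in knockout replicates 1, 2 and 3. The shares of those low genes at that ratio ran from 27.7% to 30.6%. The knockout libraries were thus somewhat deeper (mean 0.943) than the wild-type libraries (mean 0.856), and low genes are measured with less precision in wild-type replicates 1 and 3. A value of exactly 0 can be a failed estimate in these tables: the ribosomal protein gene Rpl26 was listed at 0 in wild-type replicates 2 and 3 and in knockout replicate 1, and at 30.0 FPKM in knockout replicate 3.

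Genes with a mean FPKM of at least 0.5 over the 6 libraries were tested, which left 14176 genes. Knockout was compared with wild type by limma 3.58.1 in R 4.3.3, on log2(FPKM + 1), with a prior variance that follows the mean level. The test was two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. Changes are given on the log2(FPKM + 1) scale, which understates the change of genes of low expression. For 3 libraries against 3 an exact permutation test of a single gene cannot go below 0.1, so the reported p-values are limma's. FPKM values are given as mean ± SD with n = 3 per genotype. Python 3.11.15 with pandas 2.3.3 and scipy 1.17.1 was used for joining, permutation tests and plots.

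Before the data were examined, 25 gene lists were fixed: rod and cone phototransduction, the photoreceptor ribbon synapse, transport of lipid-modified proteins, Müller glia, reactive gliosis, the JAK-STAT and NF-kB pathways, interferon response, complement, microglia, lymphocytes and neutrophils, chemokines, cell death, immediate early genes, bipolar, amacrine, horizontal and ganglion cells, pigment epithelium, lens, vessels, optic nerve glia with cornea or ciliary body, red blood cells, and neighbours of Unc119 on its chromosome. Together they hold 579 genes, of which 461 were tested. The lists are not independent, as some genes are in more than 1. This holds for 7 of the 28 gliosis members, 5 of the 43 JAK-STAT members and 4 of the 40 NF-kB members. Lists with at least 3 tested members were compared with the other genes by limma's camera, with a preset correlation of 0.01 between genes, two-sided and adjusted over the 24 lists tested. Camera with an estimated correlation, and fry, which asks whether the genes of a list move on balance in 1 direction, were run beside it. Members past the threshold are counted after adjustment over all genes and, separately, adjusted over the list alone.

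The genes to name were also set before the data were examined. They are Unc119, the 6 called genes with the largest rise and the 6 with the largest fall whose genotypes do not overlap (predicted and unnamed genes left out), up to 2 called members of each list or, where none was called, the member with the highest mean FPKM, and 11 genes fixed by name (Gnat1, Opn1mw, Opn1sw, Gnat2, Gfap, Stat3, Nfkb1, Rela and Unc119b, with 2 more that are not reported here). Other genes named below were chosen after their values were seen.

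Coordinates are those of GENCODE M21 on GRCm38, the assembly also called mm10. Of the symbols listed, 23276 matched 1 gene there, and 13632 of the tested symbols did. The annotation used by the authors can differ from it.

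The fit was tested on simulated data of 14176 genes with the observed means and spreads, in which 200 genes were changed. Of genes changed 1.5-fold, 65.7% were recovered, of those changed 2-fold 74.6%, and of those changed 4-fold 87.9%. Among genes with a wild-type level of at least 5 FPKM these shares were 79.2%, 95.7% and 97.5%. Of the 165 calls made, 13 were false. The data gave 33 calls, so the adjusted threshold asked for a smaller unadjusted p there than in the simulation. The simulated libraries also held no differences in lens RNA or sex shared across genes. The shares recovered can therefore be too high for the data. In 60 simulated sets with no change, camera with the preset correlation called a list in 5, and at most 2 lists in any of them. With the interferon list raised by 0.5 log2 units it gave an adjusted p of 5.4e-35, and 0.0047 with an estimated correlation. The simulated genes varied independently of each other. In the data the estimated correlation was 0.26 in the gliosis list, 0.45 in the rod list and 0.83 in the lens list. The simulation therefore cannot tell how often camera calls lists of correlated genes.

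Alternatives were another pseudocount (0.1), no filter and a stricter filter (mean FPKM of at least 2), median-of-ratios and quantile normalization, a prior variance without a trend, a robust prior, library weights, leaving out each library in turn, and the replicate number as a block. Fits with a sex term, with the lens level of each library as a term, and without short RNA genes were added after the data were seen. So was a fit of the gliosis, complement, microglial and interferon levels per library with a sex term, with libraries as replicates. Sex was read from Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty. The lymphocyte and neutrophil list could not be tested, because no member passed the filter.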

Results

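mRNA of the mouse retina was profiled in 3 wild-type and 3 Unc119 knockout libraries to ask which genes differ when Unc119 is lost. UNC119 binds lipid-modified proteins, among them the rod transducin subunit, and helps carry them within photoreceptors. The study's title names the JAK-STAT and NF-kB pathways, so lists for both were among those fixed in advance. The mRNA levels of these genes do not measure protein or pathway activity. The 10 most abundant genes made up 8.28% to 9.57% of the FPKM sum. By Xist and the Y-linked genes, wild-type replicates 1 and 2 and knockout replicate 1 were male, and wild-type replicate 3 and knockout replicates 2 and 3 were female. The genotypes therefore differ in their share of each sex, and values within each sex are given beside the main lists.

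Unc119 (ENSMUSG00000002058.13, chromosome 11, 78343482 to 78349164, plus strand, protein coding) was lower in each knockout library than in each wild-type library. It measured 1195 ± 10.1 FPKM in wild type and 473 ± 32.8 FPKM in the knockout (SD, n = 3 each). The log2 change was −1.34 with a standard error of 0.06 (limma adjusted p = 6.6e-05), and the exact permutation test gave p = 0.1, the smallest possible for 3 against 3. The knockout libraries held 39.6% ± 2.75 (SD, n = 3) of the wild-type mean, between 37.5% and 42.7%. Transcript from the locus was therefore still measured in the knockout retina, and which exons it covers cannot be read from values per gene. The paralog Unc119b measured 13.6 ± 0.919 FPKM in wild type and 12.6 ± 0.399 FPKM in the knockout (adjusted p = 0.694).

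Most genes that passed the test were higher in the knockout retina. Edn2, which encodes endothelin 2, a peptide released by stressed photoreceptors, went from 3.13 ± 0.150 to 37.2 ± 5.34 FPKM (SD, n = 3 each), 11.9 times the wild-type mean. Fgf2, a survival factor for photoreceptors, went from 1.99 ± 0.733 to 15.5 ± 4.67 FPKM, and Gfap, the intermediate filament of reactive glia, from 7.96 ± 0.644 to 16.1 ± 0.929 FPKM. Gnb3, a transducin beta subunit on the cone list, was higher at 303 ± 9.12 against 185 ± 6.40 FPKM. In which cells it rose cannot be read from whole retina. Of the 14176 genes tested, 29 were called higher and 4 lower at an adjusted p under 0.05 by limma, 13 and 2 of them by at least 2-fold on the scale of FPKM + 1. One of the 2 is Mir6516, whose values do not support a fold, as described below. At an unadjusted p under 0.05 there were 1276 genes, 736 higher and 540 lower. The genotypes did not overlap for 15.9% of the genes, against 10% by chance. The number of genes called higher fell whichever library was left out. It was 9, 14 and 11 without wild-type replicate 1, 2 or 3, and 17, 12 and 24 without knockout replicate 1, 2 or 3. With a sex term it was 17, and with the lens level of each library as a term it was 5. Each of these fits has fewer residual degrees of freedom than the main fit, so a call can be lost without a smaller change. Fgf2 and Lrrc2 lost calls in some of them. Over all alternatives their log2 changes were 2.24 to 2.91 and 1.16 to 1.37, against 2.45 and 1.26 in the main fit.

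The log2 changes of the 6 named genes with the largest rise were 3.20 for Edn2 (SE 0.11, adjusted p = 1.5e-05), 2.45 for Fgf2 (SE 0.24, adjusted p = 0.0101), 1.46 for Lad1 (adjusted p = 0.0101), 1.36 for Tnnt2 (adjusted p = 0.0303), 1.33 for Cebpd (adjusted p = 0.0412) and 1.26 for Lrrc2 (adjusted p = 0.0045). Lad1 encodes the basement membrane protein ladinin and Tnnt2 cardiac troponin T. Lad1 measured 0.415 ± 0.0725 FPKM in wild type and 2.92 ± 0.584 FPKM in the knockout, and Tnnt2 0.453 ± 0.268 and 2.68 ± 0.266 FPKM (SD, n = 3 each), so both were near the filter in wild type. They lie on the same strand of chromosome 1, 3011 bases apart (Lad1 135818598 to 135833342, Tnnt2 135836354 to 135852260). Edn2 lies on chromosome 4 (120161206 to 120167360, plus strand) and Gfap on chromosome 11 (102887336 to 102900912, minus strand). Fgf2 (chromosome 3, 37348346 to 37410108, plus strand) shares 5199 bases with Nudt6 on the opposite strand. Nudt6 measured 4.03 ± 1.38 FPKM in wild type and 12.7 ± 3.85 FPKM in the knockout (log2 change 1.45, adjusted p = 0.0864). Since the strand setting of the counting is not given in the sources used here, the 2 genes cannot be fully told apart. The call of Fgf2 was lost without wild-type replicate 1 (adjusted p = 0.0565) or 3 (adjusted p = 0.0642) and with the lens term (adjusted p = 0.0856), and that of Lrrc2 with the lens term (adjusted p = 0.0590). Lad1, Tnnt2 and Cebpd lost theirs without several single libraries and with the replicate block, with adjusted p up to 0.0859, 0.232 and 0.258 over all alternatives.

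Besides Unc119, the genes called lower were Smug1, Nxnl2 and Mir6516. Smug1, a uracil DNA glycosylase of base excision repair, measured 65.2 ± 3.92 FPKM in wild type and 48.4 ± 1.51 FPKM in the knockout (log2 change −0.42, SE 0.06, adjusted p = 0.0408). Nxnl2, which encodes a rod-derived cone viability factor, measured 62.7 ± 2.65 and 47.1 ± 2.28 FPKM (log2 change −0.41, SE 0.05, adjusted p = 0.0412). Either call was lost when any single library was left out, and with the replicate block (adjusted p = 0.154 for both). Mir6516, a microRNA gene of 110 bases on chromosome 11 (117077348 to 117077457) inside Snhg20, was listed at 44.8, 34.2 and 42.5 FPKM in wild-type replicates 1, 2 and 3 and at 0 in each knockout library. Multiplied by relative depth, its value was 34.2 in each wild-type library, and in wild-type replicate 3 it equalled the value of Mir199b, another gene of that length. No fold is given for it.

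**Figure D1:**
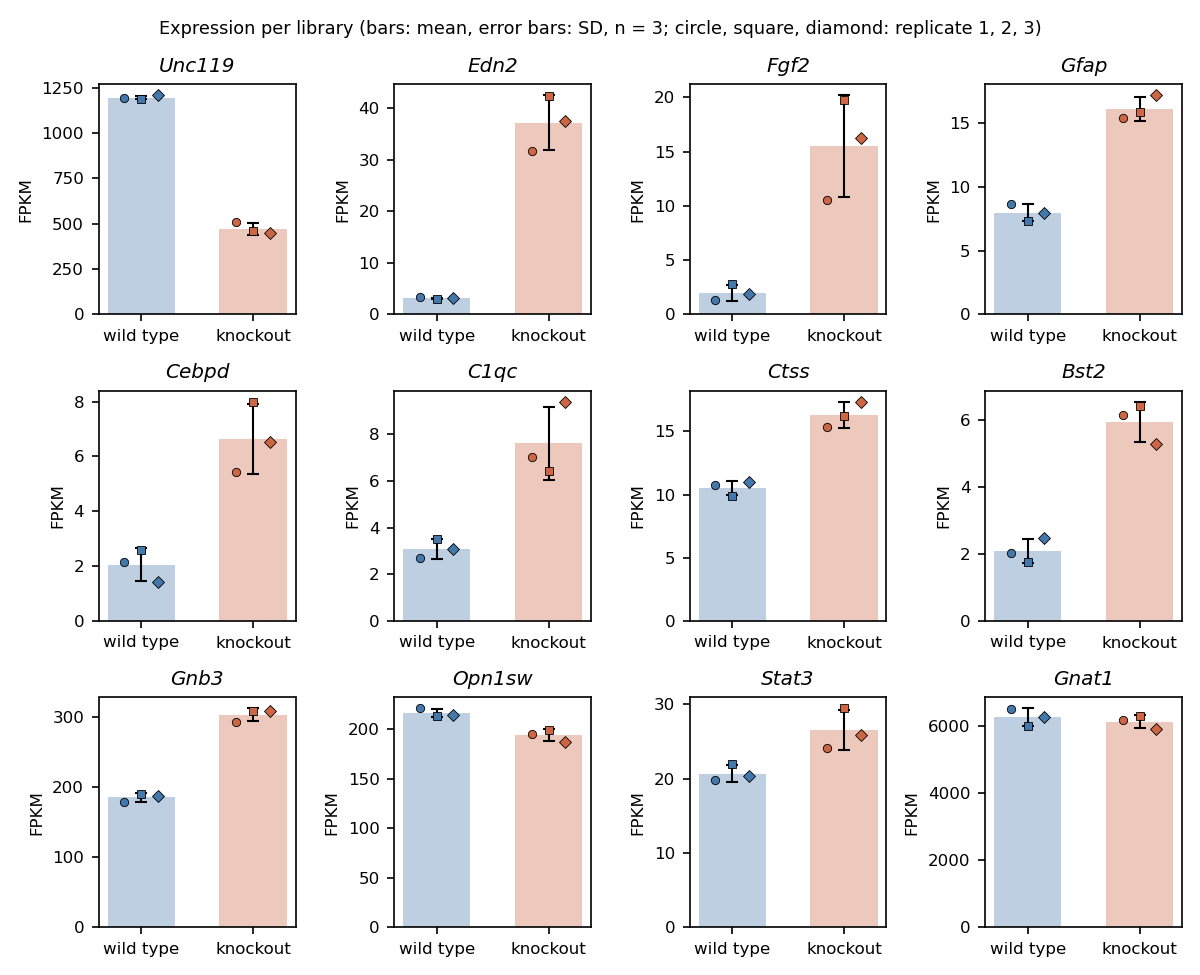
FPKM of 12 genes in each library, on linear axes from 0, with wild type in blue and knockout in red. Bars are means of n = 3, error bars are SD, and points are the libraries. Unc119 lies between 449 and 510 FPKM in the knockout libraries against 1187 to 1206 in wild type, Edn2, Fgf2, Gfap, Cebpd, C1qc, Ctss, Bst2 and Gnb3 are higher in each knockout library, Opn1sw is lower and Stat3 higher in each but neither passed after adjustment over all genes, and Gnat1 overlaps.

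The reactive gliosis and retinal stress list rose in the knockout retina. Of its 25 tested members 24 were higher, with a median log2 change of 0.55, and 5 rose after adjustment over all genes: Edn2, Fgf2, Cebpd, Serpina3n and Gfap. Adjusted over the list alone, 15 rose, among them the acute-phase gene Lcn2 (2.51 ± 0.554 to 5.94 ± 0.719 FPKM, SD, n = 3 each), the oncostatin M receptor Osmr (2.17 ± 0.422 to 4.69 ± 1.11 FPKM), and Socs3, a feedback inhibitor of cytokine signalling (1.28 ± 0.0891 to 2.40 ± 0.764 FPKM). Cebpd, a transcription factor of the acute-phase response, measured 2.06 ± 0.591 and 6.65 ± 1.28 FPKM, and Serpina3n, an inhibitor of serine proteases with near copies in the genome, 4.42 ± 0.427 and 10.5 ± 1.55 FPKM. Camera gave an adjusted p of 3.9e-22, and fry, which does not compare the list with other genes, 0.0312. The call was lost with an estimated correlation (adjusted p = 0.191). The median of the list relative to the wild-type mean was 0.29, 0.49 and 0.75 in knockout replicates 1, 2 and 3, and between −0.02 and 0.04 in the wild-type libraries. Knockout replicate 3 also had by far the most lens RNA, as described below, and without it the list median was 0.35 (adjusted p = 2.4e-22), as it was 0.34 with the lens term. The list for optic nerve glia with cornea or ciliary body was also higher in each knockout library, at 0.19, 0.29 and 0.18 against −0.14 to 0.07 in the wild-type libraries, so RNA of other eye tissue in all 3 is not excluded for this list or the immune lists. The change was 0.29 within males and 0.60 within females, each with only 1 library on 1 side. Gfap and Edn2 kept their call without any single library, and Gfap lost it with the lens term (adjusted p = 0.0607). The log2 change of Gfap was 0.93 in the main fit and 0.88 to 1.01 over all alternatives.

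Immune lists moved in the same direction. The interferon response list rose, with 26 of 27 tested members higher and a median of 0.25 (camera adjusted p = 1.6e-10, and 0.191 with an estimated correlation). Its called member was Bst2, an interferon-induced membrane protein that tethers viruses, at 2.09 ± 0.355 FPKM in wild type and 5.93 ± 0.592 FPKM in the knockout (SD, n = 3 each, log2 change 1.17, adjusted p = 0.0116). There were 8 members that rose adjusted over the list alone: Bst2, Ifitm3, Irf1, Gbp2, Lgals3bp and the antigen presentation genes B2m, H2-K1 and H2-D1. The complement list rose, with all of its 14 tested members higher and a median of 0.26 (camera adjusted p = 8.3e-08, and 0.214 with an estimated correlation). C1qc, a chain of the complement starter C1q, was called (3.09 ± 0.413 to 7.62 ± 1.57 FPKM, adjusted p = 0.0423), and adjusted over the list alone 5 rose, C1qc with C1qa, C1qb, Serping1 and C4b. C4b is also a member of the gliosis list. It has a near copy in the genome, so its value is uncertain. The microglia and macrophage list rose, with 21 of 23 tested members higher and a median of 0.40 (camera adjusted p = 2.3e-08, and 0.214 with an estimated correlation). Ctss, the lysosomal protease cathepsin S, was called (10.5 ± 0.554 to 16.3 ± 1.01 FPKM, log2 change 0.58, adjusted p = 0.0303), and adjusted over the list alone 5 rose, among them Ctss, Tyrobp, Lyz2 and Aif1.

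Within males and within females the median changes were 0.20 and 0.39 for the interferon list, 0.27 and 0.55 for complement, and 0.14 and 0.46 for microglia. Each of the 3 lists had its highest level in knockout replicate 3, the library with the most lens RNA, and without it the medians were 0.23, 0.31 and 0.25, each with an adjusted p of 2.6e-07. The medians depended on the settings too. For complement it was 0.39 without wild-type replicate 3, 0.49 without knockout replicate 1 and 0.92 with the stricter filter, for interferon 0.48 with pseudocount 0.1 and 0.50 with the stricter filter, and for microglia 0.23 with no filter, 0.26 with library weights and 0.22 with the lens term, all still called. C1qc and Ctss lost their calls when any single library was left out, with adjusted p up to 0.245 and 0.231 over all alternatives, and Bst2 lost its call without wild-type replicate 1 or 2 or knockout replicate 1 or 2 and with a sex term (adjusted p = 0.0506). With the replicate block C1qc (adjusted p = 0.135), Ctss (adjusted p = 0.108) and Bst2 (adjusted p = 0.0969) were not called. Markers of lymphocytes and neutrophils stayed under the filter, with a highest mean of 0.415 FPKM among the 17 members listed, so none of them was tested. That mean was of S100a9, at 0 in each wild-type library and 0.83, 1.26 and 0.40 FPKM in knockout replicates 1, 2 and 3. S100a8 went the other way, at 0, 0.65 and 0.81 FPKM in wild-type replicates 1, 2 and 3 and 0 in each knockout library. The chemokine list was not called (8 tested members, median 0.17, adjusted p = 0.380), and its most abundant member Cx3cl1, fractalkine, measured 33.6 ± 0.678 and 31.2 ± 2.21 FPKM (SD, n = 3 each).

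Genes of the JAK-STAT pathway did not pass camera as a list. Of the 32 tested members 16 were higher and 16 lower, the median log2 change was 0.00 and the mean 0.12, and camera gave an adjusted p of 0.0938 (0.315 with an estimated correlation). Fry did not call the list in 1 direction (adjusted p = 0.0958). It did call it as changed in either direction (adjusted p = 0.00044), as it called 15 of the 24 lists. Of the 32 members, 9 rose and 2 fell with genotypes that did not overlap, against 15.9% of all genes tested. No member passed after adjustment over all genes. Adjusted over the list alone, 4 rose, among them Osmr, the kinase Jak3 (1.10 ± 0.0694 to 2.67 ± 0.504 FPKM, SD, n = 3 each) and the transcription factor Stat3. Osmr and Stat3 are also members of the gliosis list and count there too. Stat3 measured 20.7 ± 1.10 FPKM in wild type and 26.5 ± 2.70 FPKM in the knockout (log2 change 0.34, 95% interval 0.15 to 0.52, adjusted p = 0.284 over all genes). Each knockout library was above each wild-type library. Stat3 overlaps Stat5a on the opposite strand, and Stat5a was the lowest of the list (log2 change −0.31). Pias3, the most abundant member, measured 54.9 ± 5.99 and 51.2 ± 1.83 FPKM. The list was called without knockout replicate 1 (median 0.03, adjusted p = 0.0249) and with no filter on low values (median 0.03, adjusted p = 0.0362).

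The NF-kB pathway and target list rose by camera with a small median of 0.10 (adjusted p = 0.0153), and the call was lost with an estimated correlation (adjusted p = 0.312). Of its 26 tested members 15 were higher and 11 lower, and none passed after adjustment over all genes. Fry called the list as changed in either direction (adjusted p = 0.0073), but not in 1 direction (adjusted p = 0.0909). Adjusted over the list alone, 4 rose: the adhesion molecule Icam1 (0.138 ± 0.0718 to 0.901 ± 0.267 FPKM, SD, n = 3 each), Bcl3, an atypical IkB protein (0.155 ± 0.0685 to 0.938 ± 0.429 FPKM), and the receptors Tnfrsf1a (2.81 ± 0.485 to 5.10 ± 0.797 FPKM) and Ltbr (1.75 ± 0.330 to 3.25 ± 0.406 FPKM). Bcl3 is also a member of the gliosis list. The subunits themselves did not pass: Nfkb1 measured 5.69 ± 0.689 and 5.58 ± 0.347 FPKM (log2 change −0.02, 95% interval −0.25 to 0.22, adjusted p = 0.968), and Rela 11.8 ± 0.480 and 12.6 ± 1.20 FPKM (log2 change 0.09, 95% interval −0.10 to 0.28, adjusted p = 0.755). Tnfaip3, an inhibitor of the pathway and the most abundant member, measured 101 ± 5.43 FPKM in wild type and 85.9 ± 9.17 FPKM in the knockout (log2 change −0.23, adjusted p = 0.497). The list call was lost without knockout replicate 2 (median 0.06, adjusted p = 0.197), without knockout replicate 3 (median 0.01, adjusted p = 0.213), with a sex term (adjusted p = 0.0732) and with the stricter filter, where the median was −0.02 (adjusted p = 0.232). It was kept at medians of 0.05 with no filter and 0.06 without wild-type replicate 1.

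The lists of photoreceptor genes changed by small amounts. The rod phototransduction and outer segment list fell by camera, with a median log2 change of −0.04 and 20 of 30 members lower (adjusted p = 0.0084, and 0.531 with an estimated correlation), and no member passed after adjustment over all genes. The rod transducin gene Gnat1 measured 6277 ± 257 FPKM in wild type and 6143 ± 206 FPKM in the knockout (SD, n = 3 each, log2 change −0.03, 95% interval −0.18 to 0.11, adjusted p = 0.903). In the rod list 1 member fell adjusted over the list alone, the potassium channel subunit Kcnv2 (167 ± 3.90 to 142 ± 7.02 FPKM). The rod list lost its call without wild-type replicate 1 (median −0.01, adjusted p = 0.183), without knockout replicate 3 (median 0.00, adjusted p = 0.213) and with the lens term, where its median was above 0 (0.01, adjusted p = 0.940). Its median was lower than in the main fit in other settings, at −0.07 without wild-type replicate 2 (adjusted p = 1.6e-05), −0.07 without knockout replicate 1 (adjusted p = 5.9e-04) and −0.11 with quantile normalization (adjusted p = 7.0e-05). The photoreceptor ribbon synapse list fell by camera with a median of −0.06 and 16 of 20 members lower (adjusted p = 0.0054, and 0.328 with an estimated correlation), and lost its call without knockout replicate 3 (adjusted p = 0.0619) and with the lens term (adjusted p = 0.243), and without wild-type replicate 3 its median was −0.04 (adjusted p = 0.0296). Cacnb2 and Rims2 fell adjusted over the list alone, and Snap25, the most abundant member, measured 731 ± 31.6 and 688 ± 10.7 FPKM.

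The cone list as a whole did not pass (19 tested members, median −0.06, adjusted p = 0.213), yet its member Gnb3 rose by 0.71 on the log2 scale (SE 0.04, adjusted p = 0.0012) and was called in all 18 settings of the gene test. Gnb3 lies on chromosome 6 (124834240 to 124840275, minus strand). The median of the cone list was −0.11 without knockout replicate 2 (adjusted p = 0.0688), and −0.02 without wild-type replicate 2 (adjusted p = 0.450) or with the lens term (adjusted p = 0.468). Of the 19 members 14 were lower, the lowest Pde6h, a cone phosphodiesterase subunit (log2 change −0.21). Opn1sw, the short-wavelength cone opsin, measured 216 ± 4.22 FPKM in wild type and 194 ± 6.03 FPKM in the knockout (SD, n = 3 each), lower in each knockout library but without passing the test (log2 change −0.16, 95% interval −0.25 to −0.06, adjusted p = 0.355). The middle-wavelength opsin Opn1mw measured 63.1 ± 2.47 and 66.0 ± 6.99 FPKM (adjusted p = 0.840), and cone transducin Gnat2 85.0 ± 8.47 and 79.0 ± 2.32 FPKM (adjusted p = 0.700). The list for transport of lipid-modified cargo was not called (15 tested members, median −0.03, adjusted p = 0.466), and its most abundant member Tulp1 measured 568 ± 15.2 and 631 ± 29.5 FPKM (adjusted p = 0.454).

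Among the inner retina lists, retinal ganglion cells fell by camera with a median log2 change of −0.10 and 14 of 18 members lower (adjusted p = 0.0080, and 0.515 with an estimated correlation), with no member passing over all genes or over the list alone. Neurofilament light chain Nefl measured 160 ± 8.30 FPKM in wild type and 152 ± 2.45 FPKM in the knockout (SD, n = 3 each). That call was lost without wild-type replicate 1 (median −0.04, adjusted p = 0.356) and with a sex term (adjusted p = 0.0558). Horizontal cells (11 tested members, median −0.14, adjusted p = 0.0612), bipolar cells (20 members, median −0.04, adjusted p = 0.0994) and amacrine cells (19 members, adjusted p = 0.316) were not called. Horizontal cells were called without wild-type replicate 1 (adjusted p = 0.0443), without knockout replicate 1 (adjusted p = 0.0238), with quantile normalization (adjusted p = 0.0381) and with no filter (adjusted p = 0.0347), and bipolar cells without wild-type replicate 1 (adjusted p = 0.0443). The amacrine median was −0.04, its mean 0.01 and its test pointed down. The most abundant members were Sept4 at 107 ± 1.51 and 97.2 ± 5.83 FPKM, the transducin-related Gng13 at 233 ± 27.5 and 219 ± 17.3 FPKM, and calretinin, Calb2, at 209 ± 15.3 and 195 ± 6.70 FPKM. The bipolar gene Igfn1 fell adjusted over the list alone (7.57 ± 0.677 to 5.02 ± 0.283 FPKM). The Müller glia identity list was not called (20 tested members, median 0.09, adjusted p = 0.195), except without knockout replicate 1 (adjusted p = 0.0381), and glutamine synthetase, Glul, measured 857 ± 31.6 and 793 ± 7.56 FPKM.

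Cell death genes were not called (17 tested members, median −0.04, mean 0.01, adjusted p = 0.981), with Ddit3, a transcription factor of the unfolded protein response, at 45.1 ± 3.38 FPKM in wild type and 41.6 ± 6.27 FPKM in the knockout (SD, n = 3 each). Neither were immediate early genes (16 tested members, median 0.06, adjusted p = 0.380), with Ier3 at 49.4 ± 5.72 and 42.3 ± 4.95 FPKM, although Junb rose adjusted over the list alone (10.6 ± 1.12 to 16.3 ± 1.61 FPKM). Neighbours of Unc119 on chromosome 11 were not called (42 tested members, median 0.05, adjusted p = 0.0536). That list was called without wild-type replicate 2 (adjusted p = 0.0397), with quantile normalization (adjusted p = 0.0302) and with the stricter filter (adjusted p = 0.0351), and it holds the lens gene Cryba1.

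**Figure D2:**
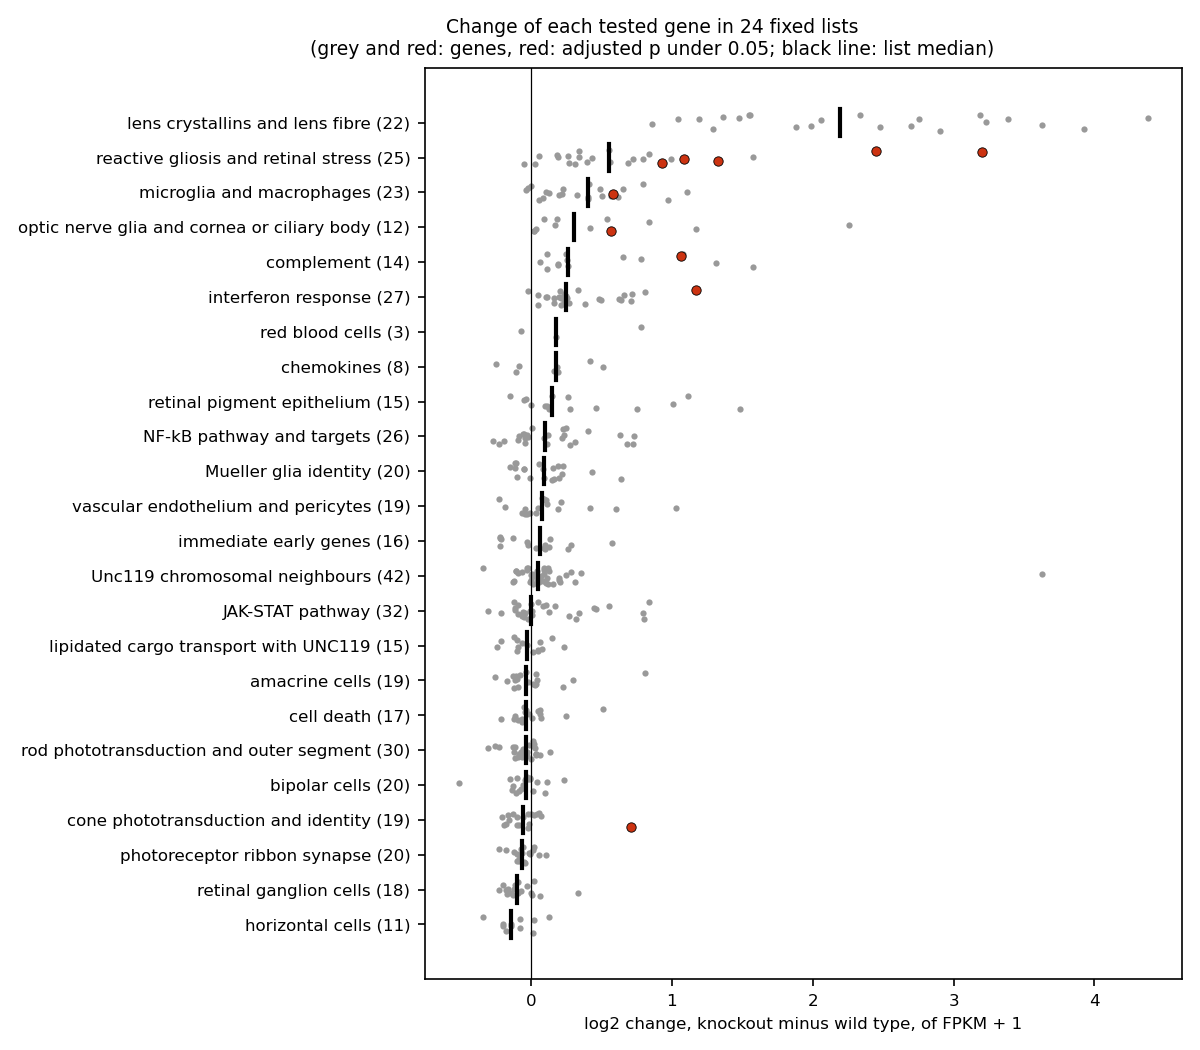
Log2 change of FPKM + 1, knockout minus wild type, on the horizontal axis, for the tested genes of 24 fixed lists, with the number tested in brackets and the vertical scatter within a list added for display. Black lines are list medians and red points the genes with an adjusted p under 0.05. The gliosis list has a median of 0.55 and 5 red points, and the lens list a median of 2.196 and no red point.

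Lens genes differed between single libraries, while the list for optic nerve glia with cornea or ciliary body was higher in each knockout library. The lens list, crystallins and lens fibre genes, rose by camera with a median log2 change of 2.196 (22 tested members, adjusted p = 2.3e-08, and 0.440 with an estimated correlation), or 3.50 with pseudocount 0.1 and 1.48 without knockout replicate 3 (adjusted p = 4.2e-04), while no member passed after adjustment over all genes or over the list alone. All 22 lens genes had their highest value in knockout replicate 3, and 21 had their lowest in wild-type replicate 3, though a value of 0 can be a failed estimate in these tables. Alpha-crystallin A (Cryaa) was at 38.5, 246 and 0 FPKM in wild-type replicates 1, 2 and 3 and at 93.8, 174 and 5296 FPKM in knockout replicates 1, 2 and 3. Lens genes made up 0.0515%, 0.247% and 0.00877% of the FPKM sum in the wild-type libraries and 0.0899%, 0.205% and 3.54% in the knockout libraries. The change of the list was −0.29 within males and 4.72 within females. The list for optic nerve glia with cornea or ciliary body rose, with all of its 12 tested members higher and a median of 0.30 (adjusted p = 0.0031, and 0.191 with an estimated correlation), and its median was 0.19 without knockout replicate 3 (adjusted p = 0.0034), 0.15 with no filter, 0.18 with the stricter filter and 0.20 with a sex term. Of the 12 members 2 had genotypes that did not overlap, against 15.9% of all genes tested. Its called member was the epithelial keratin Krt18 (86.3 ± 7.74 to 128 ± 7.84 FPKM, SD, n = 3 each, log2 change 0.57, adjusted p = 0.0379), which lost the call without wild-type replicate 2 or 3 or knockout replicate 1 or 2, with adjusted p up to 0.187 over all alternatives. Krt18 measured 134, 131 and 119 FPKM in knockout replicates 1, 2 and 3, so it was lowest of these in the library with the most lens RNA. The rise of this list alone therefore does not show that other eye tissue was carried along.

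The pigment epithelium list was not called (15 tested members, median 0.15, adjusted p = 0.0976), but was with the replicate block (adjusted p = 0.0213) and without knockout replicate 1, where its median was 0.59 (adjusted p = 1.7e-07). Its level relative to the wild-type mean was −0.48 in that library, and 0.58 and 0.35 in knockout replicates 2 and 3. Transthyretin, Ttr, measured 20.7 ± 6.15 FPKM in wild type and 26.8 ± 13.5 FPKM in the knockout (SD, n = 3 each). Vessel genes were not called (19 tested members, median 0.08, adjusted p = 0.142), except with the stricter filter (adjusted p = 0.0163), and Vtn, vitronectin, measured 458 ± 7.74 and 496 ± 9.01 FPKM. Red blood cell genes were not called (3 tested members, median 0.18, adjusted p = 0.316), with Bpgm at 30.2 ± 0.762 and 28.7 ± 2.17 FPKM, although the haemoglobin gene Hbb-b1 rose adjusted over the list alone (3.42 ± 1.04 to 6.53 ± 1.44 FPKM).

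**Figure D3:**
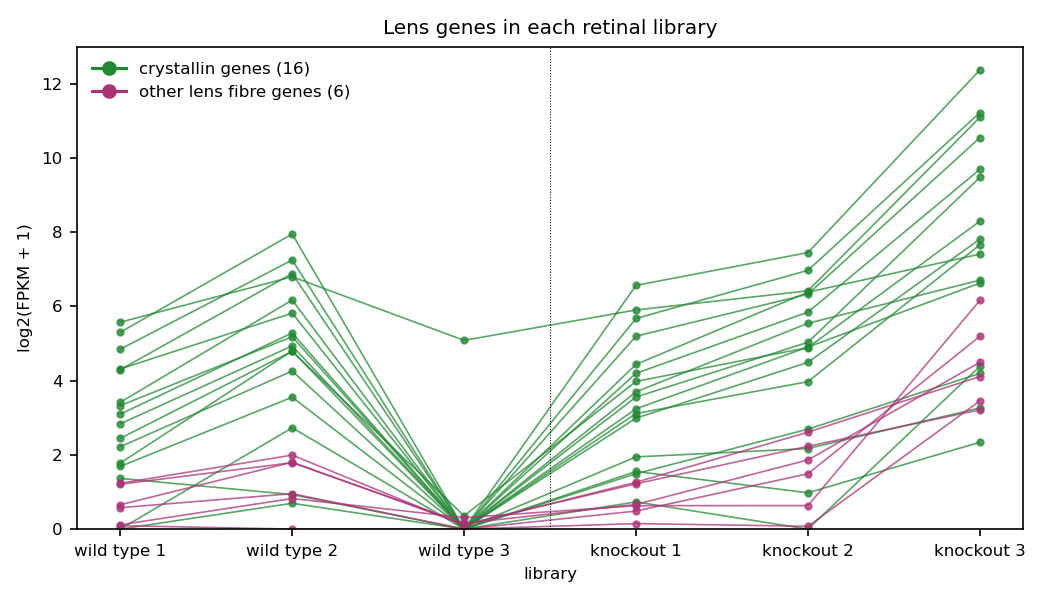
Log2 of FPKM + 1 of the 22 lens genes in each of the 6 retinal libraries, with 16 crystallin genes in green and 6 other lens fibre genes in purple, each line joining the values of 1 gene. Each of the 22 genes has its highest value in knockout replicate 3.

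Of the 24 lists tested, camera with the preset correlation called 7 higher and 3 lower, and none with an estimated correlation, where the smallest adjusted p was 0.191. By fry, 1 list was called higher (gliosis), none lower, and 15 were called as changed in either direction. Among the 15 were the JAK-STAT and NF-kB lists, and also those of amacrine and bipolar cells.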

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

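The fits with a sex term, with a lens term and without short RNA genes were chosen after seeing the data. Unc119 stayed lower and past the threshold in every alternative (log2 change −1.39 to −1.28, adjusted p 2.4e-06 to 0.0028). All 33 called genes kept their sign wherever tested. Their genotypes did not overlap, so leaving out a library could not turn the sign. Calls were lost more readily, 22 of the 33 without wild-type replicate 1 and 26 with a lens term. Edn2, Gnb3, Racgap1, Tagln2 and Unc119 were called in all 18 settings. Leaving out single libraries gave 9 to 24 genes higher and 2 to 4 lower, with fewer libraries in the fit, and lists lower went from 1 to 4. Genes higher numbered 17 with no variance trend, 17 with a sex term, 5 with a lens term and 13 at 2-fold or more of FPKM + 1. Genes lower numbered 2 with no filter, 2 with a sex term, 2 with a lens term and 2 at 2-fold or more. With the replicate block the counts were 13 and 2, and with a robust prior they were higher, 36 and 6. With genotype means subtracted, the same-numbered libraries correlated at 0.07, −0.09 and −0.12, and not each library correlated best with its own number. Lens RNA and sex also vary between libraries, so these values cannot tell whether same-numbered libraries were handled together. The no-filter fit tests more genes (18240), and the cause of the other changes was not tested. Without short RNA genes 31 rose and 3 fell. With a lens term 1 list was lower, with an estimated correlation 0 were higher and 0 lower, and by fry 1 and 0. The lens list was not tested under the lens term, which is built from it. Medians of some lists that were not called moved widely over the alternatives, for chemokines from −0.00210 to 0.226, for red blood cells from −0.0926 to 0.432, for the pigment epithelium from −0.0437 to 0.586 for horizontal cells from −0.170 to −0.0310 and for cones from −0.106 to −0.0156. Smaller medians that moved by over 1.5 times were those of bipolar cells (−0.0661 to −0.00927), amacrine cells (−0.0759 to −0.0182), immediate early genes (−0.00629 to 0.0918), Müller glia (0.000801 to 0.119), vessels (0.0120 to 0.112), neighbours of Unc119 (0.0243 to 0.0681) and JAK-STAT genes (−0.0278 to 0.0536).

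Several results near 0 turned direction by their test, and the cause was not tested. The cell death list, with a median of −0.0372 and a test that pointed up, had a test that pointed down at medians of −0.0414 with pseudocount 0.1, −0.0457 with the stricter filter, −0.0469 with quantile normalization, −0.0282 with library weights, −0.0372 with the replicate block and −0.0120 with a lens term. With no filter the red blood cell list was at −0.00173. With a lens term the lipidated cargo list was at −0.0248, Müller glia at 0.000801, pigment epithelium at −0.0373, vessels at 0.0252, Nfkb1 at 0.0717, Gnat1 at 0.0116, Bpgm at 0.00568 and Gng13 at 0.0268. With a sex term Ttr was at −0.0588. Over the single libraries left out, cell death ranged from −0.0272 to 0.00634 (turned without wild-type replicate 3, knockout replicate 2 or 3), lipidated cargo from −0.0620 to −0.00236 (knockout replicate 3), Ttr from −0.0710 to 0.719 (knockout replicate 2), Opn1mw from −0.00167 to 0.146 (knockout replicate 2), Nfkb1 from −0.0701 to 0.0636 (wild-type replicate 3, knockout replicate 2) and Gng13 from −0.148 to 0.00945 (wild-type replicate 3). Depth limits the low genes most, and its absolute value is unknown.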

Other observations

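The lens, Mir6516, sex, library and split tests below were chosen only after the values had been seen. Those on microglial markers and on genes near Unc119 were set before.

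Of the 33 called genes, 23 were in none of the fixed lists, and the genes named in this paragraph were chosen after their values were seen. Tagln2, an actin-binding protein, was higher at 25.8 ± 1.78 against 12.4 ± 1.07 FPKM (SD, n = 3 each, limma adjusted p = 0.0045), and Racgap1, a GTPase-activating protein of cell division, at 16.2 ± 0.362 against 8.19 ± 0.573 FPKM (log2 change 0.91, adjusted p = 0.0045). The transcription factors Sox30 (8.22 ± 0.288 to 17.5 ± 1.81 FPKM) and Rfx2 (2.51 ± 0.317 to 5.85 ± 0.159 FPKM), known mainly from the testis, rose, as did the stress gene Gadd45b (4.37 ± 0.260 to 10.6 ± 1.03 FPKM). The growth factor Btc rose from 4.37 ± 0.740 to 10.1 ± 1.80 FPKM, with an adjusted p of 0.0496. Also called were the hexokinase Hk1 (226 ± 6.17 to 277 ± 3.33 FPKM, adjusted p = 0.0412) and the glucokinase regulator Gckr (38.8 ± 1.24 to 60.5 ± 4.53 FPKM, adjusted p = 0.0101). Racgap1 and Tagln2 were called in all 18 settings, while Btc and Hk1 were called in 8 and 6 of the 18 settings.

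The lens genes were highest in knockout replicate 3, all 22 of them. Loss of Unc119 as the whole cause is argued against, since 0 of the 22 lay above all wild-type libraries in both knockout replicates 1 and 2. Those 2 libraries had list levels of 0.78 and 1.66, below the 1.96 of wild-type replicate 2, which has much lens RNA itself. A smaller difference between genotypes is not excluded: without knockout replicate 3 the list was still called at the preset correlation (median 1.48, adjusted p = 4.2e-04), though with all libraries the call was lost with an estimated correlation (adjusted p = 0.440). Lens tissue carried along with the dissected retina stays open: 6 of the 6 lens fibre genes that are not crystallins were highest there, but they are among the 22 that show the pattern, so this does not test it. In wild-type replicate 3, the library with the least lens RNA, only Cryab of the 22 was above 1 FPKM and 16 were listed at 0, which can be a failed estimate in these tables, so how little it held is uncertain. No other cause of the difference between libraries was tested.

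Gliosis, complement, microglial and interferon lists were higher in the knockout. Lens or other eye tissue in knockout replicate 3 as the whole cause is argued against, since all 4 lists lay above the highest wild-type library in knockout replicates 1 and 2 by more than the wild-type range. They were also called without that library, at the preset correlation, while with all libraries none was called with an estimated correlation (adjusted p 0.191 to 0.214). Unequal sexes in the groups were examined by a fit of list levels per library with a sex term. Knockout minus wild type was 0.333 (95% interval 0.109 to 0.558) for interferon and 0.291 (0.0523 to 0.530) for microglia, intervals above 0. It was 0.452 (−0.00541 to 0.909) for gliosis and 0.412 (−0.178 to 1.003) for complement, intervals that include 0. The fit left 3 residual degrees of freedom. The intervals are not adjusted over the 4 lists, which were picked after they were seen to rise. Unequal sexes as the whole cause therefore stay open for all 4. With a sex term in the gene fit the medians of the gliosis and complement lists were 0.47 and 0.21. Both stayed called by camera at the preset correlation (adjusted p = 3.4e-19 and 9.8e-07). Within males the comparison rests on 1 knockout library, and within females on 1 wild-type library. More microglia and macrophages with unchanged expression per cell stay open. The 5 homeostatic markers had a median log2 change of 0.20 (SD 0.12) and the other 18 members 0.45 (SD 0.34). A two-sided permutation test of the difference in means, not medians, gave p = 0.167 over 100000 resamples across genes, which are not independent replicates. Other eye tissue in all 3 knockout libraries was not tested and stays open, as the list for optic nerve glia with cornea or ciliary body was higher in each of them. Loss of Unc119 stays a hypothesis, since age and batch are not given in the sources used here.

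Mir6516 had the smallest p of all genes. FPKM times relative depth was 34.2 in each wild-type library, so the call may rest on 1 fragment in each of them, at a step that Mir199b shows too in wild-type replicate 3. Not all genes of that length keep to the step: Mir719 was at 21.7 FPKM in knockout replicate 2. The value at 0 in the knockout cannot be read as loss of the transcript at this depth.

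The 6 libraries make 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 33 genes and the highest other 8, which was the split by sex. It gave 10 lists and the highest other 9, and in either case 1 of the 10 splits, the real one, reached its own value.

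The 115 tested genes within 5 Mb of Unc119 had a median absolute log2 change of 0.09, at the 90.5th percentile of 10000 random lists matched on mean expression, and 0 of them were called by limma (13 at an unadjusted p under 0.05), with the smallest adjusted p, 0.177, for Gemin4.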
